A study of Mus musculus with 20 samples.

How the data were processed

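The samples were testes of adult male mice that carried the RiboTag allele and a Cyp17 iCre driver. RiboTag is a ribosomal protein that gains an HA epitope in cells expressing Cre recombinase, so that polysomes of those cells, here Leydig cells, can be precipitated with an antibody against HA. Per the labels' protocols, spermatogenesis was synchronized with an inhibitor of retinoic acid synthesis, given at 100 µg per g from 2 days after birth for 7 days. All-trans retinoic acid (200 µg) followed at 9 days after birth, and testes were taken 42 to 50 days later. The testes fell into 5 windows of the cycle of the seminiferous epithelium (stages XII-II/III, II/III-VI, VI-VIII, VIII-X and X-XII). Per the labels' protocols, 1 testis per time point was homogenized, 50 µl of the homogenate gave the total testis RNA and the rest went into the immunoprecipitation (IP). For replicate 1 of total testis XII-II/III the labels conflict: the source field reads X-II/III, while title and stage field read XII-II/III, which was used. With 2 replicates per window and fraction there were 10 groups and 20 arrays (GeneChip ST 1.0), each from 100 ng of amplified RNA.

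The deposited values are linear intensities of summarized probe sets, made by RMA per the submitters' processing notes. The version and software were not given in the sources used here. The values themselves showed 4 sets of 5 arrays, each holding the 5 windows of a fraction and replicate, that appear to have been normalized separately. Between 8.38% and 13.5% of the value pairs of 2 arrays within a set were exactly equal, against 6 equal values among 3708775 pairs across sets. Of 28856 probe sets, 28856 carried values in the first IP set, 26006 in the first total set, 23528 in the second IP set and 26013 in the second total set. The lowest maximum over a listed probe set's 5 arrays was 33.0, 100.0, 208 and 100.0 intensity units in these sets, so the lists looked to have been filtered at different floors. The median log2 intensity over probe sets listed in all arrays was 9.74, 9.43, 9.99 and 9.42. Differences between IP and total were tested against 0, and the median difference of all genes and the counts after rescaling are given beside them. The highest intensity of an array lay between 22180 and 27275.

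Gene symbols came from the platform's annotation. A single symbol was held by 21789 probe sets, several by 1621 and none by 5446, and only the first kind was used. Entrez identifiers of 21698 probe sets matched the current gene table, and 0 symbols changed. Of several probe sets of a gene the one with the highest mean over all arrays was kept, which concerned 869 genes or 5.08% of those with a listed probe set. Values were taken as log2, and a gene was tested if it was listed in all 20 arrays and its mean in at least 1 of the 10 groups passed the 25th percentile of all log2 values (8.20), which left 15651 genes. Members of the fixed lists outside these genes took no part in the comparisons.

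Tests used limma 3.58.1 in R 4.3.3 on a model with a mean for each of the 10 groups (10 residual degrees of freedom), moderated by eBayes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05. IP was compared with total testis as the mean of the 5 IP groups minus the mean of the 5 total groups, in log2. Its SEs and p-values take the 10 arrays of a fraction as independent. These arrays lay in separately normalized sets, so both are likely too small. A moderated F test over the 5 windows was run within IP, within total testis and on the difference between the fractions (interaction). The window with the highest group mean was called the peak window, its difference from the mean of the other 4 windows is given with its standard error (SE), and the adjusted p beside it is that of the F test. The amplitude was the highest minus the lowest group mean. Each window was also tested against the mean of the other 4.

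The 14 gene lists were tested with limma's camera, with a preset correlation of 0.01 and again with a correlation estimated from the arrays, adjusted over lists or over lists and 10 window contrasts (140 tests). For IP against total testis limma's fry was run as well, adjusted over lists. It tests a list against no difference rather than against the other genes. A one-sided Fisher's exact test asked whether a list held more genes with a window effect than the other tested genes. The lists covered steroidogenesis, other Leydig cell markers, cholesterol synthesis and uptake, retinoid metabolism and signalling, secreted growth factors, immediate early genes, the circadian clock, Sertoli cells, peritubular myoid cells, macrophages, endothelial cells, spermatogonia, spermatocytes and spermatids. Lists, tests and the rule for naming genes were fixed before the data were examined. The rule took any list member, the 10 genes with the largest and the 10 with the smallest called difference between fractions whose 10 IP arrays lay apart from all 10 total arrays, and the 10 genes of smallest interaction p. For each peak window it took the 4 genes with the largest called difference whose 2 peak arrays lay above the other 8 arrays of the fraction, over all genes, over genes higher in IP, and in total testis. Predicted-only symbols and olfactory or vomeronasal receptors were passed over. Other genes named in the closing section were chosen after their values were seen, as stated there.

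Both fractions of a testis came from the same homogenate, and arrays were matched to testes by window and replicate number. Arrays so matched deviated together: with set means removed, the correlations of the 5 pairs of deviations lay between 0.300 and 0.519. For 20 pairs from different windows they ran from -0.405 to 0.406 (median -0.131), so the ranges overlap. Across windows the replicate number alone did not pair testes evenly. Correlations ran from -0.006 to 0.551 within IP (median 0.232) and from -0.062 to 0.666 within total testis (median 0.040). Blocks by replicate number, by testis and by jointly normalized set were fitted as alternatives. The labels do not say whether the replicates of a group were different animals, so p-values measure the spread between these samples.

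The statistics were tested on simulated data that kept each gene's mean, its residual spread and the deviations of the jointly normalized sets. Among 15651 genes, of which 50 were changed at each size, the comparison of fractions recovered 84% of the genes changed by 0.5, and 100% of those changed by 1 or more, with 3 false calls. The simulated set deviations cancelled within each fraction, so no scaling offset between IP and total testis was simulated. These false calls thus do not bear on such an offset. For the window effect in IP the shares were 0% at 0.5, 58% at 1 and 100% at 2 and at 3, with 0 false calls. With a block for each jointly normalized set they were 58% at 0.5, 82% at 1 and 100% at 2 and at 3, with 11 false calls. Intensity arrays give no count depth, and the number of arrays limits the precision. Alternatives changed the scaling (quantile normalization, median centring), the filter (none, or the 50th percentile at 9.36), array weights, the variance prior, the summary of probe sets, the blocks and the arrays used, each array also being left out in turn. Figures were drawn with matplotlib 3.10.9.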

Results

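Transcripts on Leydig cell polysomes and transcripts of the whole testis were measured in synchronized mouse testes at 5 windows of the seminiferous cycle, as 10 IP and 10 total testis arrays, 2 per group. Leydig cells are the androgen-producing cells between the tubules, and the synchronized tubules make it possible to ask whether their transcripts follow the stage of the germ cells beside them. After filtering, 15651 genes were compared.

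The first comparison asked which transcripts the IP enriched over the homogenate it was made from. Transcripts of steroid hormone synthesis were far more abundant in IP. All 11 tested genes of the steroidogenesis list were higher, with a median log2 difference of 2.39. Star (probe set 10571054), which moves cholesterol into mitochondria, was higher by 3.18 ± 0.11 (SE, n = 10 arrays per fraction in separately normalized sets, limma adjusted p = 1.01e-13), and Hsd3b1 by 3.77 ± 0.08. Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, was higher by 2.48 ± 0.079, and Hsd17b3, which makes testosterone, by 2.84 ± 0.086. Nr5a1, the transcription factor that drives many of these genes, was higher by 2.78 ± 0.062. Cyp17a1, whose promoter drives the Cre, rose by 1.03 ± 0.067, the smallest difference of the list. The 9 tested genes among the other Leydig cell markers were all higher, with a median of 3.40, among them Ces1d (3.93 ± 0.083), Hao2 (3.79 ± 0.074), the estrogen sulfotransferase Sult1e1 (3.47 ± 0.073) and the estrogen receptor Esr1 (3.40 ± 0.075). Of 21 cholesterol genes 19 were higher and 1 lower, with a median of 2.06. Msmo1 (3.58 ± 0.066), Hsd17b7 (3.21 ± 0.095) and Lss (2.17 ± 0.08), enzymes of cholesterol synthesis, were higher, while the hormone-sensitive lipase Lipe fell by 0.78 ± 0.078 (limma adjusted p = 8.25e-08). All 3 lists were called by camera (adjusted p = 3.02e-05 each). With an estimated correlation the calls were lost (adjusted p = 0.284 with an estimated correlation for the first 2 lists, 0.349 for the cholesterol list). The counts were the same when adjusted over the list alone. By fry, which tests against no difference, the 3 lists were called (adjusted p = 3.81e-12, 4.81e-13 and 1.87e-10). So were all 14 lists (fry adjusted p up to 0.0107). Fry thus does not single out these 3, and it depends on the scaling between the fractions.

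The 10 largest differences among genes whose IP arrays all lay above all total arrays belonged to Cd36 (4.17 ± 0.14), a fatty acid transporter, Adgrg7 (4.10 ± 0.075), the complement components C2 (4.09 ± 0.075) and C1s1 (4.08 ± 0.066), Itih2, Pon3, Aff2, Ces1d, Serpinb1a and Nat8f5 (3.90 ± 0.12). At the other end, Ppp1r2-ps9 (-2.46 ± 0.11) and Asb12 (-2.33 ± 0.055) were lowest, followed by Pln, Pudp, Atp6ap1l, Lypd10, Ube2dnl1, Cpn1, Cox7b2 and Ms4a5 (-2.05 ± 0.074). These 20 genes had limma adjusted p-values of at most 2.53e-09 (Ube2dnl1).

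Germ cell transcripts were depleted in IP. Of 18 spermatid genes 16 were lower and 0 higher, with a median of -0.86. Acrv1, an acrosomal protein (-1.77 ± 0.16), the sperm ion channel subunit Catsper1 (-1.62 ± 0.12), Akap4 (-1.08 ± 0.072) and the protamine Prm1 (-0.54 ± 0.075) were among them. Of 16 spermatocyte genes 15 were lower and 0 higher, with a median of -0.52. The synaptonemal complex genes Sycp3 (-1.55 ± 0.097) and Sycp1 (-1.15 ± 0.098) were lower. Camera called both lists (adjusted p = 8.23e-07 for spermatids and 2.26e-05 for spermatocytes), and both calls were lost with an estimated correlation (adjusted p = 0.284 with an estimated correlation). Spermatogonial genes went both ways, with 3 of 12 higher and 5 lower (camera adjusted p = 0.4001). Their median was -0.03 and their mean 0.34, so these differed in sign. Kit (3.21 ± 0.087), Etv5 (1.97 ± 0.091) and Zbtb16 (1.83 ± 0.13) were higher, while Sohlh2 fell by 1.33 ± 0.081.

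Peritubular myoid and macrophage genes were lower as groups. Of 8 myoid genes 5 were lower and 1 higher, with a median of -0.66, and the smooth muscle actins Acta2 (-1.73 ± 0.054) and Actg2 (-1.34 ± 0.094) were lower. Of 10 macrophage genes 8 were lower and 2 higher, with a median of -0.63, with C1qb (-1.44 ± 0.084) and Lyz2 (-1.19 ± 0.082) as examples. Cd14 was higher by 0.89 ± 0.094. Camera called both lists (adjusted p = 0.00569 and 0.00412), and neither with an estimated correlation (adjusted p = 0.284 and 0.344 with an estimated correlation). Median centring gave the macrophage list an adjusted p of 0.050, just missing the threshold, and the filter at the 50th percentile gave both lists 0.0850. The higher calls of Myh11 (0.67 ± 0.22) and Mrc1 (0.49 ± 0.13) were lost after quantile normalization (adjusted p = 0.404 and 0.591) and median centring (0.401 and 0.733). Endothelial genes were split, with 3 of 8 higher, 2 lower and a median of -0.04, against a mean of 0.26 (camera adjusted p = 0.772). Cdh5 was higher by 1.76 ± 0.10.

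The remaining lists were not called by camera. Of 13 clock genes 10 were higher and 0 lower, with a median of 0.78, among them Hlf (1.73 ± 0.071) and Nr1d1 (1.57 ± 0.099), and the list missed the threshold (adjusted p = 0.0519, against 0.0251 after median centring). Of 20 secreted growth factors 12 were higher and 2 lower (adjusted p = 0.157). Csf1 (2.25 ± 0.085), Kitl (2.14 ± 0.076) and Cxcl12 (2.01 ± 0.11) were higher, and Igf1 fell by 0.49 ± 0.07. Adjusted over the list alone, 11 were higher and 1 lower. Of 18 immediate early genes 10 were higher and 1 lower (adjusted p = 0.157), with Myc (2.31 ± 0.11) and Jun (1.83 ± 0.093) higher and Klf4 lower (-0.62 ± 0.11). Adjusted over the list alone, 9 were higher and 1 lower. Of 14 Sertoli cell genes 9 were higher and 0 lower (adjusted p = 0.157), 8 when adjusted over the list alone, with Trf (1.36 ± 0.12) and Clu (0.86 ± 0.059) as examples. Kitl belongs to the Sertoli cell list as well. Of 20 retinoid genes 10 were higher and 5 lower (adjusted p = 0.764). Adh1 (3.67 ± 0.065), Dhrs3 (3.08 ± 0.12) and the retinaldehyde dehydrogenase Aldh1a1 (1.79 ± 0.056) were higher, and Rbp4 (-1.29 ± 0.12) and Crabp1 (-1.13 ± 0.091) lower. After median centring these splits changed to 9 higher and 8 lower for growth factors, 8 and 9 for immediate early genes, 9 and 3 for clock genes, 5 and 3 for Sertoli cell genes, 9 and 9 for retinoid genes, 2 and 6 for endothelial genes and 3 and 9 for spermatogonial genes.

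Among all genes, 7839 were higher and 4166 lower in IP, or 65.3% of 12005 calls higher. The median of all genes was 0.20, and IP and total testis lay in separately normalized sets of arrays, so the balance depended on the scaling. It was 5816 higher and 7271 lower (44.4% higher) after quantile normalization, where the median of all genes was -0.08. After median centring it was 4764 and 9208 (34.1%), with a median of -0.26. Larger differences leaned to IP: 2836 genes were higher and 844 lower by at least 1, and 834 and 17 by at least 2. With the normalization set as a random block (correlation 0.636) 6302 genes were higher and 2944 lower, and Klf4, Myh11 and Mrc1 were the genes named for this comparison that were no longer called (adjusted p = 0.120, 0.408 and 0.294). The SEs and p-values given above for IP against total testis come from the model without that block and are likely too small.

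**Figure D1:**
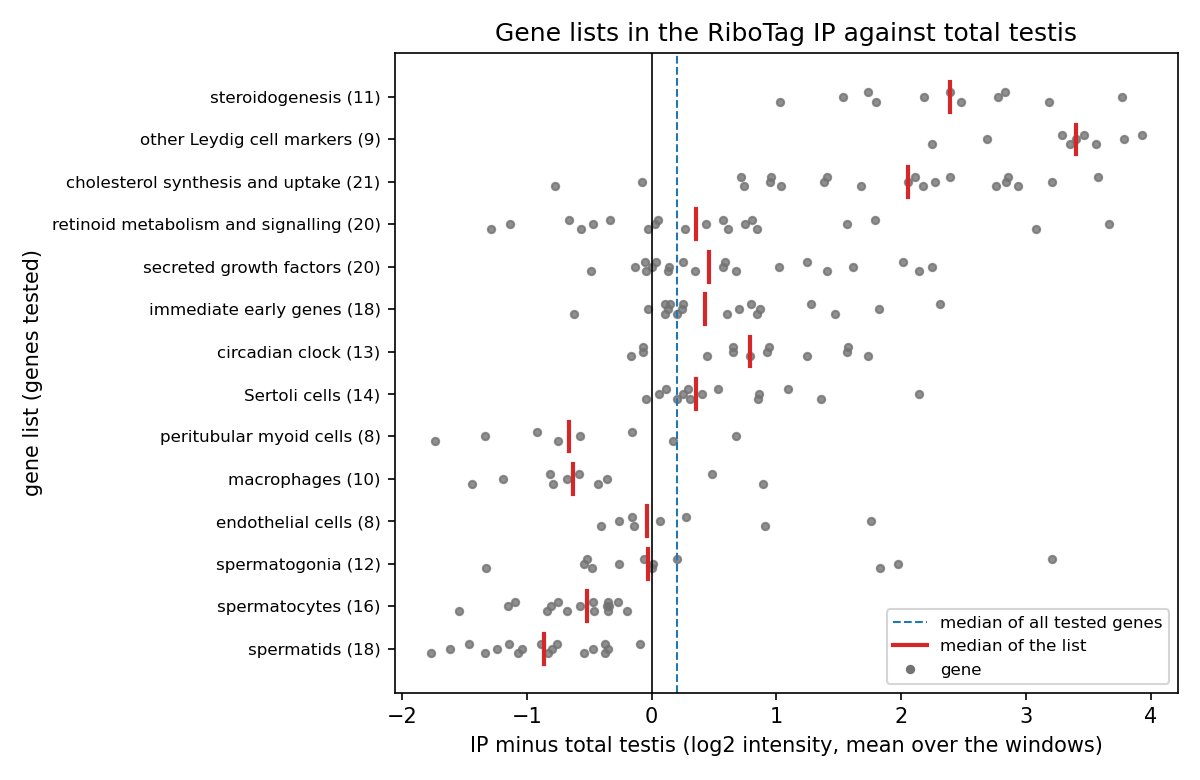
IP minus total testis (log2 intensity, mean over the 5 windows) of each tested gene of the 14 lists, with list medians as red bars and the median of all tested genes, 0.20, as a dashed line. The medians of the steroidogenesis, other Leydig and cholesterol lists lie at 2.39, 3.40 and 2.06, and those of spermatocytes and spermatids at -0.52 and -0.86; retinoid, growth factor and immediate early lists change their balance of higher and lower genes with median centring.

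The second comparison asked which transcripts in the IP differed between the windows of the cycle. Germ cell genes were among those with large differences. Among spermatid genes, Catsper3 peaked in VI-VIII at 2.23 ± 0.26 above the other windows (SE, n = 2 arrays per window, limma adjusted p = 9.54e-06), Spaca1 in VI-VIII at 1.90 ± 0.26 and Acrv1 in VI-VIII at 1.83 ± 0.28. The transition protein Tnp1 (1.63 ± 0.43) and the protamine Prm1 (0.61 ± 0.13) peaked in VIII-X. Of 18 spermatid genes 9 were called, 11 when adjusted over the list alone, more than among the other tested genes (one-sided Fisher's exact test, adjusted p = 1.07e-04). Of 16 spermatocyte genes 4 were called, namely Pou5f2, Rec8, Smc1b and Sycp1, and 7 when adjusted over the list alone (Fisher adjusted p = 0.221). The spermatocyte gene Pou5f2 peaked in X-XII at 0.95 ± 0.21 and Sycp1 in II/III-VI at 0.77 ± 0.17. Of the 20 fits that each left out an array, 16 ended the Smc1b call and 1 the Rec8 call, both being weakest without VI-VIII replicate 2 of IP (adjusted p = 0.183 and 0.0670).

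In all, 1388 genes (8.87%) were called, with peaks in XII-II/III for 46, II/III-VI for 294, VI-VIII for 428, VIII-X for 453 and X-XII for 167. In 856 of them the amplitude was at least 1. The number depended on the model: 407 genes were called with array weights, 762 with the 10 IP arrays alone, 2166 after median centring, 2347 after quantile normalization and 3004 with a block for each jointly normalized set (the set block). The main model shares a gene's spread between IP and total testis, so its window p-values in IP may be too small. Genes lower in IP than in total testis were called more often (930 of 4166, 22.3%) than genes higher in IP (207 of 7839, 2.64%; odds ratio 10.6, 95% interval 9.05 to 12.4, two-sided Fisher's exact test p = 1.52e-259, genes not being independent). With the set block the counts were 1500 lower and 850 higher genes, a smaller contrast. By window, Gem peaked in XII-II/III (0.97 ± 0.18). Cntn6 (2.14 ± 0.26), Ppil6 (2.05 ± 0.27) and Iqca (2.03 ± 0.31) led in II/III-VI. In VI-VIII the leading genes were Klk1b1 (2.30 ± 0.43), Fam24b (2.27 ± 0.20), Spata31 (2.18 ± 0.27) and Tex36 (2.11 ± 0.19), and in VIII-X Spata31d1c (2.14 ± 0.41), Trp53tg5 (2.10 ± 0.44), Faiml (2.09 ± 0.47) and Prss52 (2.09 ± 0.42). Bhlhe40 (2.04 ± 0.16), Nr4a1 (1.81 ± 0.22), Amotl2 (1.38 ± 0.15) and the salt-inducible kinase Sik1 (1.37 ± 0.16) led in X-XII. Klk1b1 was not called in 1 of the 20 fits, that without VI-VIII replicate 2 of IP (adjusted p = 0.489).

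Among genes higher in IP, 207 differed between windows, against 45 with array weights, 67 with the 10 IP arrays alone, 386 after quantile normalization and 341 without II/III-VI replicate 2 of IP. Their peaks fell in XII-II/III for 21, II/III-VI for 42, VI-VIII for 35, VIII-X for 85 and X-XII for 24. Bhlhe40 (probe set 10540472), a transcriptional repressor tied to the circadian clock, was 2.04 ± 0.16 higher in X-XII (limma adjusted p = 8.14e-06), and Amotl2 1.38 ± 0.15, the lysophospholipid transporter Mfsd2a 1.15 ± 0.18 and Bcl3 0.73 ± 0.16 peaked there too. In II/III-VI the immediate early transcription factor Egr1 was higher by 2.00 ± 0.24 (limma adjusted p = 0.000207), with Krtap6-5 (1.74 ± 0.29), Arhgap28 (1.25 ± 0.17) and Foxa3 (0.89 ± 0.18). The heparanase Hpse (1.82 ± 0.27), the plasminogen activator Plat (1.53 ± 0.31), Sdk2 (1.45 ± 0.18) and the vitamin D receptor Vdr (1.44 ± 0.21) peaked in VIII-X, but these 4 exceeded total testis by only 0.25 ± 0.10 (Sdk2) to 0.59 ± 0.15 (Hpse), and with the random set block that difference was not called (adjusted p = 0.298 to 0.541). Klk1b1, Adam8 (0.94 ± 0.20), Tmem178b (0.90 ± 0.20) and Ppp1r3a (0.87 ± 0.18) peaked in VI-VIII. Zbtb16 (0.79 ± 0.23), Fbxl7 (0.67 ± 0.14), Serpinf1 (0.60 ± 0.14) and Mvd (0.58 ± 0.13) peaked in XII-II/III. Egr1, Krtap6-5, Mfsd2a, Adam8, Tmem178b and Ppp1r3a also exceeded total testis by less than 1. For genes below that size, RNA carried over from other testis cells and a Leydig cell effect could not be told apart (closing section). Of the 207 genes, 89 remained higher in IP when the fractions were compared after median centring. Leaving out an array ended several calls, here with the number of the 20 fits and the weakest fit. Bcl3 was lost in 16 (adjusted p = 0.445 without X-XII replicate 2 of IP), Fbxl7 in 10 (0.346 without XII-II/III replicate 1) and Serpinf1 in 5 (0.155 without XII-II/III replicate 2). Lost in 2 were Mvd (0.0862 without XII-II/III replicate 1), Adam8 (0.143 without VI-VIII replicate 1) and Ppp1r3a (0.228 without VI-VIII replicate 2). Lost in 1 were Zbtb16 and Krtap6-5 (0.0589 and 0.151 without II/III-VI replicate 1) and Klk1b1 (0.489 without VI-VIII replicate 2).

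None of 11 steroidogenesis genes, 9 other Leydig markers, 20 growth factors or 8 endothelial genes passed limma's F test in IP, and 0 did when adjusted over the list alone. At an unadjusted p under 0.05 the counts were 0, 0, 2 and 0, and with the set block 0, 0, 2 (Bmp4 and Tgfa) and 1 (Egfl7). Smaller changes could be missed: 0% of simulated changes of 0.5 and 58% of those of 1 were recovered. These shares are a rough guide only, since the simulation changed fewer genes than were called here. It also gave IP and total testis the same spread. Some genes were called at smaller sizes, such as Rdh11 below. Of 18 immediate early genes 4 were called, Egr1 and Btg2 with peaks in II/III-VI, Nr4a1 in X-XII (1.81 ± 0.22, limma adjusted p = 0.000136) and Klf4 in VI-VIII (0.76 ± 0.20), 5 when adjusted over the list alone and 10 with the set block. Of 13 clock genes Per1 (0.57 ± 0.12, X-XII) and Per2 (0.71 ± 0.13, II/III-VI) were called, 4 when adjusted over the list alone and 5 with the set block. Of 20 retinoid genes 4 were called, the retinol transporter Stra6 (1.69 ± 0.30) and Rdh10 (0.98 ± 0.22) with peaks in VIII-X, Lrat (0.68 ± 0.15) in VI-VIII and Rdh11 (0.32 ± 0.099) in X-XII, also when adjusted over the list alone. Gata1 (0.77 ± 0.19, VIII-X) among 14 Sertoli cell genes, Actg2 (0.56 ± 0.17, VIII-X) among 8 myoid genes and Adgre1 (0.77 ± 0.12, II/III-VI) among 10 macrophage genes were called. Of 12 spermatogonial genes, Uchl1 (1.70 ± 0.27, VIII-X) and Zbtb16 were. Adjusted over the list alone these counts were 2, 1, 1 and 2. Fisher's test called none of these lists (adjusted p from 0.242 to 1). With single arrays left out, Btg2 was lost in 15 of 20 fits (adjusted p up to 0.279, without II/III-VI replicate 2), Actg2 and Rdh10 in 3 (0.264 without II/III-VI replicate 1 and 0.0754 without VIII-X replicate 2) and Klf4 in 2 (0.0607 without XII-II/III replicate 2). Stra6 (0.105 without VIII-X replicate 2) and Zbtb16 (0.0589 without II/III-VI replicate 1) were lost in 1.

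With a block for each jointly normalized set, which compares windows within a set only, 3004 genes were called in IP, 1348 of them shared with the 1388, and 850 of the genes higher in IP were called, or 977 with the block in both tests. Every gene named for its peak window in IP kept its call under this block, the highest adjusted p being that of Klk1b1 at 0.0443. Other alternatives ended many of them: of 62 calls of named genes, 36 were lost with array weights, among them Gem (adjusted p = 0.140), Plat (0.107), Tmem178b (0.673) and Stra6 (0.152), and 20 with the 10 IP arrays alone, among them Zbtb16 (0.0551), Serpinf1 (0.211), Foxa3 (0.0598) and Mvd (0.210). Bhlhe40, Egr1, Nr4a1, Amotl2, Mfsd2a, Arhgap28, Hpse, Sdk2 and Vdr were called in both.

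**Figure D2:**
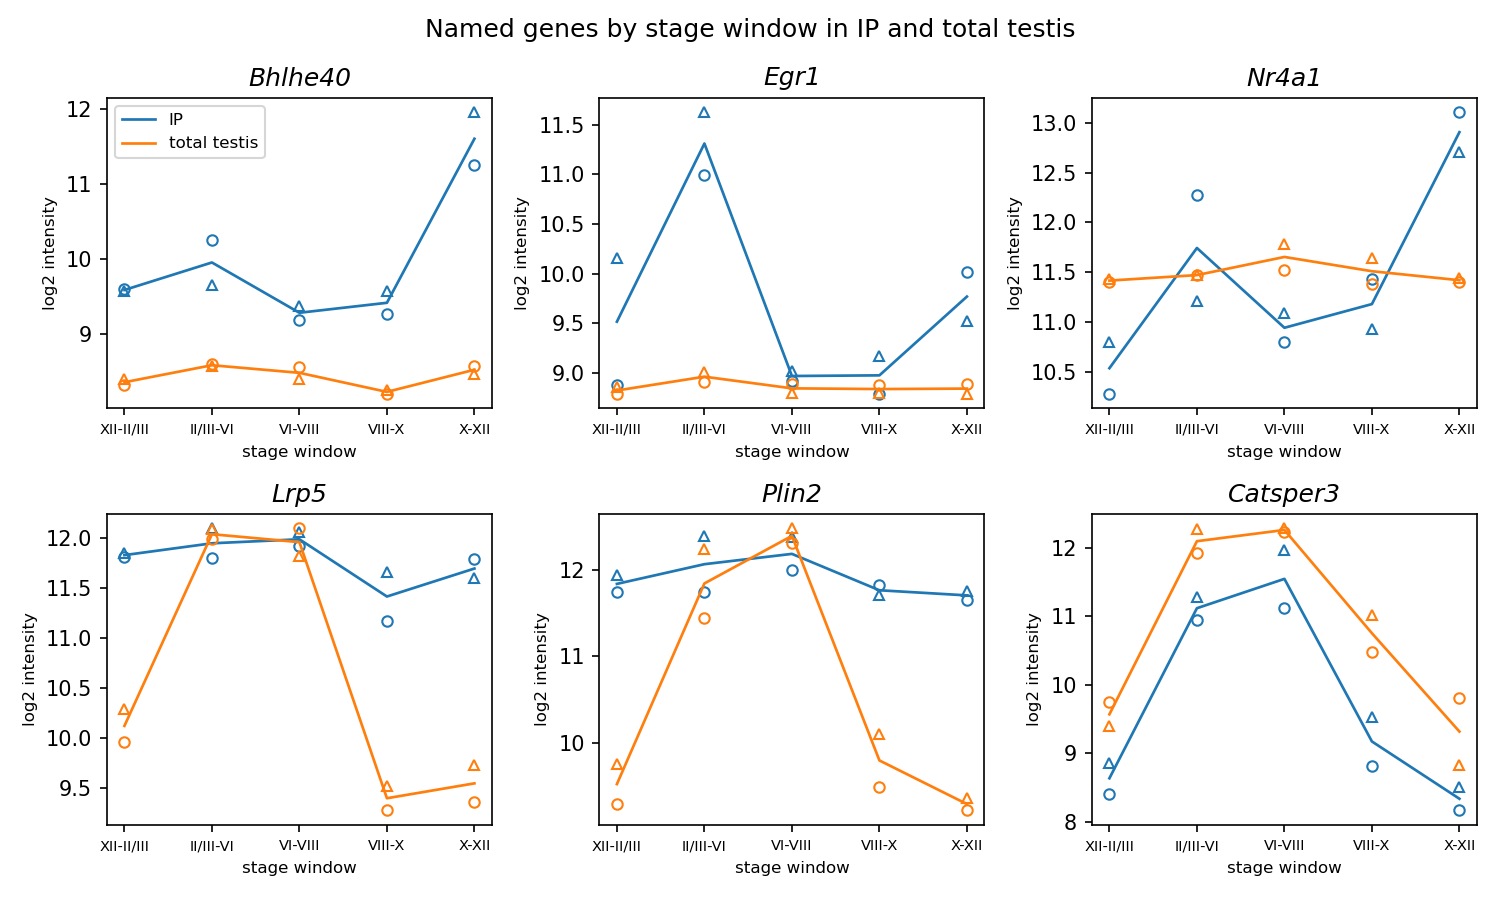
Log2 intensity by stage window of 6 named genes in IP (blue) and total testis (orange), with circles for replicate 1, triangles for replicate 2 and lines through group means. Bhlhe40 reaches a mean of 11.60 in X-XII in IP and stays between 8.23 and 8.59 in total testis, while Lrp5 and Plin2 vary in total testis and Catsper3 varies in both.

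Cholesterol genes moved together in IP. In XII-II/III all 21 genes lay above the mean of the other windows, with a median of 0.27 (camera adjusted p = 7.91e-09). In II/III-VI all lay below it, with 0 above and a median of -0.24 (adjusted p = 0.000706), and in VIII-X 2 of 21 lay above, with a median of -0.23 (adjusted p = 0.000206). With an estimated correlation none of these passed (adjusted p = 0.9904 with an estimated correlation, each). The mevalonate pathway gene Mvd (0.58 ± 0.13, limma adjusted p = 0.0129), Lss (0.49 ± 0.14), Hsd17b7 (0.55 ± 0.17) and Insig1 (0.48 ± 0.14) peaked in XII-II/III and Lipe (0.41 ± 0.14) in VIII-X. These 5 of 21 genes were called by the F test (Fisher adjusted p = 0.221), and 6 when adjusted over the list alone. The 2 falls rested on single arrays: without II/III-VI replicate 2 of IP the first had an adjusted p of 0.631, and without VIII-X replicate 1 the second had 0.519, while the rise was called in every fit that left out an array. The single gene calls were weaker. Of the 20 fits that left out an array, Lipe was lost in 18, Insig1 in 16, Hsd17b7 in 15, Lss in 14 and Mvd in 2. The weakest fit was that without XII-II/III replicate 1 of IP for Mvd, Lss, Hsd17b7 and Insig1 (adjusted p = 0.0862, 0.123, 0.136 and 0.146) and that without II/III-VI replicate 1 for Lipe (0.175). In total testis the list was not called in any window. Lists of other cells moved the opposite way in the same IP windows: spermatid and spermatocyte genes fell in XII-II/III (adjusted p = 0.0192 and 0.0396) and Sertoli cell and spermatid genes rose in VIII-X (0.000499 and 0.00933), though no list of another cell type was called in II/III-VI, and these 4 calls were lost in 5, 6, 1 and 3 of the 20 fits. None of the 4 passed camera with an estimated correlation (adjusted p = 0.9904 each), and those in XII-II/III ended with the set block (0.0686 each).

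**Figure D3:**
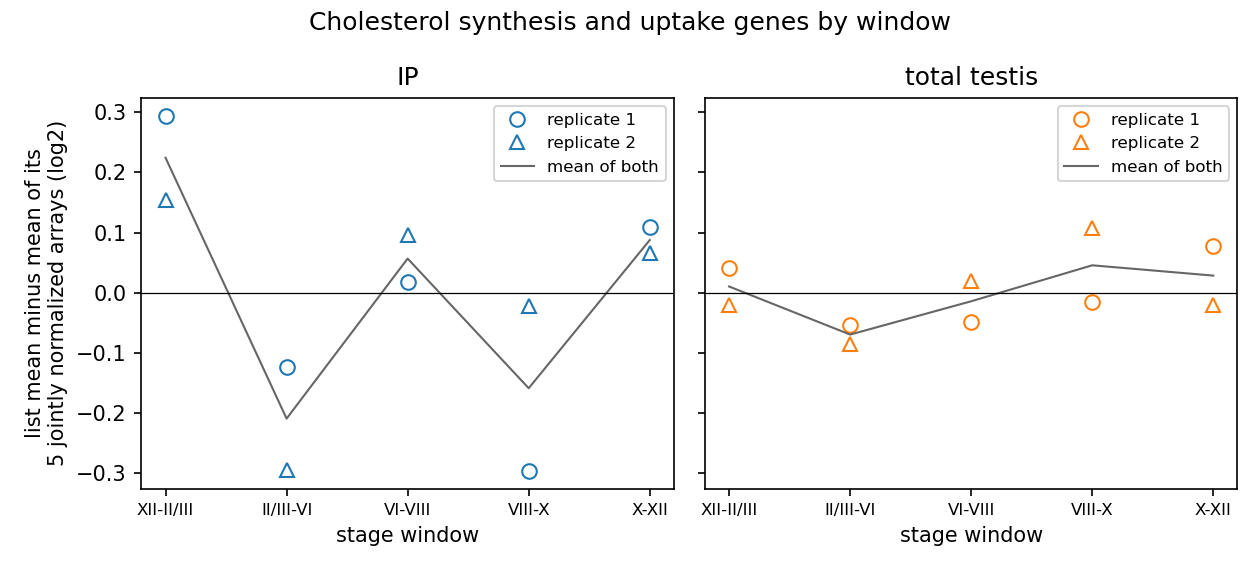
Mean log2 intensity of the 21 cholesterol genes on each array minus the mean of its 5 jointly normalized arrays, by stage window, in IP and total testis, with circles for replicate 1, triangles for replicate 2 and lines through the mean of both. In IP both arrays of XII-II/III lie above 0 (0.29 and 0.15) and both of II/III-VI below (-0.12 and -0.30), whereas in VIII-X the replicates lie at -0.30 and -0.02.

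Other lists were called in IP windows as well. Sertoli cell genes were higher in VIII-X (median 0.38, 13 of 14 above 0, camera adjusted p = 0.000499) and lower in X-XII (median -0.20, 2 above 0, 0.0148). The second call was lost in 3 of 20 fits that left out an array and turned in direction without X-XII replicate 2 (0.927), and the first was lost in 1, without VIII-X replicate 2 (0.0645). Immediate early genes were higher in II/III-VI (median 0.09, 11 of 18 above 0, 0.00541). Spermatid genes were higher in VIII-X (median 0.19, 14 of 18 above 0, 0.00933), a call lost in 3 of the 20 fits, most clearly without VIII-X replicate 1 (0.313). Spermatid and spermatocyte genes were lower in XII-II/III (medians -0.07 and -0.10, adjusted p = 0.0192 and 0.0396), and both calls ended with the set block (0.0686 each) and in 5 and 6 of the 20 fits, most clearly without XII-II/III replicate 2 (0.431 and 0.627). In sum 9 list and window pairs were called in IP and 0 in total testis, and 0 with an estimated correlation (adjusted p = 0.9904 with an estimated correlation, each). Single contrasts called 2938 gene and window pairs in IP, with 501 genes higher and 470 lower in II/III-VI and 593 and 292 in VI-VIII. In VIII-X 378 were higher and 134 lower, in X-XII 72 and 248, and in XII-II/III 14 and 236. The number of pairs was 6836 with the set block, 365 with array weights, 1431 with the 10 IP arrays alone, 4709 after median centring and 5138 after quantile normalization.

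In total testis, where germ cells make up most of the tissue, window differences were more frequent. The F test called 2885 genes (18.4%), 1368 of them with an amplitude of at least 1. Peaks fell in XII-II/III for 537, II/III-VI for 597, VI-VIII for 632, VIII-X for 694 and X-XII for 425. Aqp8 (2.50 ± 0.32, limma adjusted p = 7.52e-06), Asb15 (2.36 ± 0.34), Stambpl1 (2.29 ± 0.21) and the lipid droplet protein gene Plin2 (2.28 ± 0.21) led in VI-VIII, and Ssxb2 (2.36 ± 0.22), Tpte (2.26 ± 0.31), Iqca (2.24 ± 0.31) and Scn7a (2.07 ± 0.26) in II/III-VI. Dyrk4 (2.06 ± 0.48), Zc2hc1b (2.05 ± 0.35), the serine protease Prss52 (1.98 ± 0.42) and Cd46 (1.96 ± 0.44) led in VIII-X. In X-XII these were Gramd2 (1.45 ± 0.19), B4galt6 (1.07 ± 0.18), Kif4-ps (1.02 ± 0.19) and Rassf1 (0.84 ± 0.13), and in XII-II/III Zbtb42 (1.18 ± 0.23), Mapk11 (1.05 ± 0.22), the dynein gene Dnaic2 (1.01 ± 0.28) and Card6 (0.92 ± 0.19). The Cd46 call was lost in 2 of the 20 fits that left out an array, most clearly without VIII-X replicate 2 of total testis (adjusted p = 0.113).

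By list, 7 of 18 spermatid genes were called in total testis, with Catsper3 (1.83 ± 0.26) and Spaca1 (1.72 ± 0.26) in VI-VIII and Tnp1 (1.12 ± 0.43) in X-XII, and 8 when adjusted over the list alone. Of 16 spermatocyte genes 5 were called, with Pou5f2 (1.51 ± 0.21) in X-XII and the meiotic cohesin gene Rec8 (1.45 ± 0.20) in VI-VIII, and 8 when adjusted over the list alone. Of 20 retinoid genes 7 were called, among them Rdh10, Rxrg (0.65 ± 0.18) and Rxra (0.61 ± 0.18) in VIII-X and Lrat (1.18 ± 0.15) in II/III-VI. Of 11 steroidogenesis genes Star (0.83 ± 0.20, X-XII), Scarb1 (0.59 ± 0.15, VIII-X) and Cyb5a (0.41 ± 0.11, XII-II/III) were called, and of 9 other Leydig markers the kallikreins Klk1b24 (1.37 ± 0.21) and Klk1b27 (1.58 ± 0.33), in VI-VIII. None of these 5 differed between fractions by the interaction test (limma adjusted p from 0.123 for Cyb5a to 1). Of 21 cholesterol genes Fdps (0.76 ± 0.16), Sqle (0.66 ± 0.13) and Insig1 (0.57 ± 0.14) were called, of 20 growth factors Igf1, Pdgfa (0.65 ± 0.18) and Tgfa, and of 18 immediate early genes Jun (0.50 ± 0.16) and Klf4 (0.85 ± 0.20). Of 13 clock genes Per1 (0.70 ± 0.12), Nr1d1 (0.62 ± 0.18) and Ciart (0.71 ± 0.17) were called. Gata1 among 14 Sertoli cell genes, Adgre1 among 10 macrophage genes and Sohlh2 (0.89 ± 0.14) among 12 spermatogonial genes completed the calls, with 0 of 8 myoid and 0 of 8 endothelial genes. Apart from the germ cell lists named above, these counts were the same when adjusted over the list alone. Fisher's test called none of the 14 lists in total testis (lowest adjusted p = 0.419).

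Among these genes, leaving out an array ended the call of Igf1 in 5 of 20 fits (adjusted p = 0.213 without VI-VIII replicate 1 of total testis), Tgfa in 4 and Rxra in 3 (0.0798 and 0.148 without II/III-VI replicate 1), and Klk1b27 and Gata1 in 2 (0.307 without VI-VIII replicate 2 and 0.144 without II/III-VI replicate 2). Star (0.0564 without VI-VIII replicate 1), Klk1b24 (0.0691 without VI-VIII replicate 2) and Ciart (0.0798 without XII-II/III replicate 2) were lost in 1. With the set block 5747 genes were called, 2859 of them shared with the 2885, and the number was 5936 with array weights, 4790 with the 10 total arrays alone, 4627 after median centring and 4485 after quantile normalization. Single contrasts called 6090 gene and window pairs, with 962 genes higher and 1289 lower in VI-VIII and 939 and 1024 in II/III-VI, and 14676 pairs with the set block. In VIII-X 432 were higher and 281 lower, in X-XII 270 and 463, and in XII-II/III 168 and 262.

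The last comparison asked whether window profiles differed between IP and total testis. Most genes called in IP were called in total testis too: the overlap was 1080, where independent lists of these sizes would share 256, and 788 of the 1080 (73.0%) had the same peak window. The arrays of both fractions came from the same testes, so part of the excess may be shared sampling. With the set block the overlap was 2176, against 1103 for independent lists. The interaction was called for 8 genes. Lrp5 (probe set 10464504), a Wnt co-receptor, peaked in II/III-VI in total testis at 1.78 ± 0.15, while its highest window in IP, VI-VIII, stood out by 0.27 ± 0.15 (limma interaction adjusted p = 0.00189). Plin2 (probe set 10514221) rose in VI-VIII in total testis by 2.28 ± 0.21, against 0.34 ± 0.21 in IP (interaction adjusted p = 0.0193). Bhlhe40 was the reverse case, 2.04 ± 0.16 above the other windows in IP, whereas its highest window in total testis, II/III-VI, stood out by 0.19 ± 0.16 (interaction adjusted p = 0.0382). Aox3 and Frmd4b (adjusted p = 0.0382 each) and Stambpl1, the fatty acid elongase Elovl6 and Cldnd1 (adjusted p = 0.0466 each) had larger window differences in total testis, at 1.42 ± 0.19, 1.77 ± 0.18, 2.29 ± 0.21, 1.02 ± 0.13 and 1.36 ± 0.14. Tm2d1 and Gnpda2 came next and were not called (adjusted p = 0.0548 each). Neither were Nr4a1 (adjusted p = 0.0548), Egr1 (0.112) and Amotl2 (0.114), whose window effect was called in IP and not in total testis. Of all genes, 693 had an unadjusted interaction p under 0.05.

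The interaction calls were fragile. With a replicate block by testis 8 genes were again called, 3 of them others, but not Bhlhe40 (adjusted p = 0.0738), Aox3 (0.0589) or Elovl6 (0.0738). The number was 68 with a replicate block by number, 361 with a block for each normalized set and 613 with testis and set blocks together. It was 142 after quantile normalization, 206 after median centring, 36 with the filter at the 50th percentile, 48 with a trended, robust prior and 5 without a filter. All 8 calls were kept with the blocks by number, by set, and by testis and set together. The rescalings, the stricter filter and that prior kept them too, while 3 were lost without a filter. Leaving out single arrays gave 1 to 27 genes. Lrp5 was called in every such fit, though not with array weights (adjusted p = 0.0519), where Bhlhe40 alone was called, and Plin2 was lost in 5 of 20, most clearly without X-XII replicate 2 of IP (adjusted p = 0.0775). Bhlhe40 and Aox3 were lost in 11 of 20, Frmd4b in 12, Stambpl1 in 13 and Elovl6 and Cldnd1 in 15. The weakest fit was that without X-XII replicate 1 of total testis for Bhlhe40 (0.136) and for Aox3, Frmd4b, Stambpl1 and Elovl6 (0.134 each), and that without VI-VIII replicate 1 of total testis for Cldnd1 (0.140).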

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

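The tests of window profiles between fractions, of germ cell classes, of the size of carry-over, of the cholesterol genes in total testis, of the other lists in the cholesterol windows and of the clock genes were chosen only after the result was seen. A test of the difference between the fractions' window effects singled out 8 genes: Lrp5 (adjusted p = 0.00189), Plin2 (0.0193), Bhlhe40, Aox3 and Frmd4b (0.0382 each) and Stambpl1, Elovl6 and Cldnd1 (0.0466 each). Bhlhe40 differed more in IP (amplitude 2.32 against 0.36), and the other 7 in total testis. A block by testis, from which both fractions came, ended the calls of Bhlhe40 (limma adjusted p = 0.0738), Aox3 (0.0589) and Elovl6 (0.0738). Testis and set blocks together, chosen after seeing the data, kept all 8 among 613 calls. Lrp5 was called whichever array was left out, but not with array weights (adjusted p = 0.0519), which left Bhlhe40 alone.

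The difference between IP and total testis was set against other splits of the arrays. Exchanging fractions turns their large differences into residual spread, so the real split was likely to rank first. Fraction coincides with the separately normalized sets, so the counts cannot part fraction from scaling. They do not bear on the calls of single genes. In a model with window and side, the real split of the arrays gave 12305 genes, and among 100 splits that parted both fractions of every testis, the real one included, 1 gave as many. The highest other split gave 10144 and differed from the real one by the exchange of the fractions of 1 testis. The median of the drawn splits was 0. Splitting replicate 1 from replicate 2 gave 97 genes, and IP replicate 1 with total replicate 2 against the rest gave 563.

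Genes lower in IP gave 930 of the 1388 window effects in IP, and 1500 of 3004 with the set block, beside 207 and 850 from genes higher in IP. Over the 930 genes the median correlation of the 5 window means between IP and total testis was 0.970 (95% bootstrap interval 0.967 to 0.972, across genes, which are not independent replicates), against 0.643 for 2000 random genes and 0.907 (0.891 to 0.926) for the 207 genes higher in IP chosen in the same way, so the likeness is not particular to depleted genes. RNA of other testis cells carried into the IP is a possible explanation that needs such profiles. Tagged ribosomes in a single germ cell class stay open, since the spermatid median minus the spermatocyte median of IP minus total was -0.338 (-0.722 to 0.0868).

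The same carried-over RNA was weighed for genes higher in IP. If equal in all windows, it can give a gene at most about the total testis difference divided by the gene's enrichment, where differences are small. A large total testis difference, or a carry-over that varies between windows, can give more. Genes whose IP windows differed by at least 1 in one replicate were measured, between the same windows, in the other. For genes higher by at least 1 the IP difference exceeded that size by a median of 0.144 (0.0502 to 0.296, 105 genes) in replicate 2 and 0.290 (0.171 to 0.469, 66 genes) in replicate 1, with lower limits of 0.0184 and 0.135 after median centring. Their median total testis differences were 0.0428 and 0.00534, against 0.242 and 0.366 in IP. A carry-over equal in all windows thus leaves a part of the median IP difference unexplained. One that varied between windows was not tested, so carry-over stays open for these genes. For genes higher by less than 1 the excess was 0.142 (0.0433 to 0.204) and 0.122 (0.0573 to 0.278), but -0.101 to -0.0015 and -0.0453 to 0.0945 after centring, so carry-over and a Leydig cell effect cannot be told apart for them.

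The cholesterol genes differed by a median of 0.372 between XII-II/III and the mean of II/III-VI and VIII-X in IP. A changing share of Leydig cell RNA would move other enriched genes too, yet 10000 random lists matched on IP level and enrichment had a median of 0.120 (0.0636 to 0.173), and 99.1% lay below 0.5 times the list's value, a narrow margin to the limit of 99% set before this test. The windows were those in which the cholesterol list had been called in these data, a choice the random lists did not have. The random lists were drawn gene by gene and lack the shared movement of a pathway, so 99.1% is likely too high. The 20 steroidogenesis and other Leydig marker genes differed by a median of 0.0283. In single windows spermatid and spermatocyte genes fell where the cholesterol genes rose (XII-II/III, camera adjusted p = 0.0192 and 0.0396). Sertoli cell and spermatid genes rose where the cholesterol genes fell (VIII-X, 0.000499 and 0.00933). A changing share gives this direction to genes depleted in IP. These calls were lost in 5, 6, 1 and 3 of the 20 fits that left out an array (up to 0.431 and 0.627 without XII-II/III replicate 2, 0.0645 without VIII-X replicate 2 and 0.313 without VIII-X replicate 1 of IP). With an estimated correlation camera called none of them (adjusted p = 0.9904 each), and the set block ended those in XII-II/III (0.0686 each). The Sertoli cell list was not depleted in IP, so its rise is less clear. Of its 14 genes 9 were higher and 0 lower, or 5 and 3 after median centring. Between the windows compared here, the medians of the 7 lists of other cell types ran from -0.0992 (spermatocytes, -0.346 to 0.0212) to 0.0211 (macrophages, -0.0416 to 0.0660), every interval including 0, and steroidogenesis genes rose by 0.0462 (0.0126 to 0.187). For IP minus total testis the spermatocyte interval was -0.359 to -0.0653, the direction of a changing share. The steroidogenesis interval was -0.263 to -0.0345, the opposite direction, and those of the remaining cell type lists included 0. A changing share is thus argued against as the whole cause, within the limits given. A part stays open, since the matched lists moved by 0.120 (0.0636 to 0.173) where the cholesterol list moved by 0.372. Carry-over equal in all windows is argued against by total testis, where the list differed by 0.0251 (paired difference 0.342, 0.223 to 0.453). Time of day stays open: over the 10 IP arrays, set means removed, the list's mean followed the clock gene Arntl with r = 0.710 (permutation p = 0.0374, adjusted over 13 clock genes 0.271) and rho = 0.697 (p = 0.0399, adjusted 0.346), and r = 0.545 without the 2 arrays farthest from the median of Arntl. A stage effect on cholesterol synthesis in Leydig cells may be part of the pattern, and its falls rest on single arrays. The rise rests in part on the XII-II/III replicate 1 IP array, from a testis whose total testis labels conflict on the window.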

How the results depend on the processing

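The block within each fraction (a term per jointly normalized set), the random set block, the block by testis and set, the fits with every gene listed in a fraction and the fits without both arrays of the second II/III-VI testis were chosen after seeing the data. Of 6901 values of 217 single results under the alternatives, 6463 kept their direction and their side of the threshold, 400 lost a call, 27 gained it, 2 reversed and 9 counts moved. Both reversals concerned lists: endothelial genes between IP and total testis with the filter at the 50th percentile (adjusted p = 0.752) and Sertoli cell genes in X-XII without IP X-XII replicate 2 (0.927, the lowest over the left-out arrays being 1.34e-07 without IP X-XII replicate 1). The cause was not tested for either, nor for the counts below, except where a fold limit leaves fewer calls.

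A replicate block changed the window effects. A block within each fraction raised the window effect from 1388 to 3004 genes in IP, from 207 to 977 among genes higher in IP and from 2885 to 5747 in total testis. It raised window contrasts to 6836 and 14676 and the interaction from 8 to 361. A block by testis and set gave 613 interaction genes and one by replicate number 68. The block by testis was run for 97 of the single results, of which it changed the interaction calls of Bhlhe40, Aox3 and Elovl6 and no other. The interaction count stayed at 8, so 3 other genes gained a call, and 12040 genes differed between the fractions, against 12005.

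Quantile normalization gave 7271 genes lower in IP, 2347 and 4485 window effects in IP and total testis, 386 among genes higher in IP, 5138 and 10773 window contrasts and 142 interaction genes. Median centring gave 4764 higher and 9208 lower genes, 2166 and 4627 window effects, 4709 and 11314 contrasts and 206 interaction genes. Array weights gave 407 and 5936 window effects, 45 among genes higher in IP, 365 and 16548 contrasts and 1 interaction gene, Bhlhe40, and ended 36 of 62 window calls of named genes in IP. A fraction's 10 arrays alone gave 762 and 4790 window effects, 67 among genes higher in IP and 1431 and 12520 contrasts. With every gene listed in them these were 770 and 4864 effects and 1456 and 12853 contrasts. Fewer arrays do not account for the rise of window effects from 2885 in total testis. They may account for a part of the fall from 1388 in IP. The main model shares a gene's spread between the fractions. Its window p-values may thus be too small in IP and too large in total testis. A size of at least 1 left 3680 genes between the fractions (2836 higher, 844 lower) and 856 and 1368 window effects. The interaction count was 5 without a filter, 36 with the filter at the 50th percentile and 48 with a trended, robust prior.

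Leaving out single arrays, where the lone array of a group is assumed to vary like the other groups, gave 11673 to 12308 genes between the fractions (7443 to 8278 higher, 3976 to 4380 lower). Window effects were 1215 to 1578 in IP and 2187 to 3181 in total testis, and window contrasts 2343 to 3211 and 4172 to 7059. Among genes higher in IP there were 157 to 341, the 341 without IP II/III-VI replicate 2. The interaction count was 1 to 27 (27 without IP II/III-VI replicate 2), and every array moved it by over 1.5 times except IP XII-II/III replicate 1, IP II/III-VI replicate 1, IP VIII-X replicate 2 and Total VI-VIII replicate 2. List calls were 7 to 8 between the fractions and 5 to 11 by window, with 5 without IP VIII-X replicate 1. Signal over background limits genes near the floors at which the sets were listed, which differed between sets, so weak genes absent from a set were not compared.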

Other observations

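The comparison of replicate profiles and the look at list members outside the tested genes were chosen only after the data were seen. Across genes, which are not independent replicates, the II/III-VI replicate 2 IP array correlated at 0.763 with VI-VIII replicate 1 and at 0.70 with II/III-VI replicate 1. In total testis the same testis gave 0.836 and 0.854. The X-XII replicate 2 total array correlated at 0.859 with XII-II/III replicate 1 and at 0.789 with X-XII replicate 1, whereas the IP array of the same testis gave 0.429 and 0.496. The XII-II/III replicate 1 total array in this comparison is the one whose labels conflict (source field X-II/III), so its window, and with it the total testis values of XII-II/III, is less sure. Both fractions of a testis came from the same homogenate, so the doubt extends to the XII-II/III replicate 1 IP array. That array held the larger cholesterol list value of XII-II/III in IP (0.294 above its set mean, against 0.154 in replicate 2).

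Stra8, the only list member listed in a fraction but outside the genes tested in all arrays, differed between windows in a limma fit of the 10 total arrays alone (adjusted p = 0.00422), with the highest mean log2 intensity in VIII-X (8.71) and the lowest in II/III-VI (7.53).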
